A study of Gallus gallus with 6 samples.

How the data were processed

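RNA was measured in the uterovaginal junction of breeder hens in 2 groups of 3 libraries, taken at a thermoneutral 23 °C or after 6 h at 36 °C. Per the labels' protocols, total RNA was extracted from 24 tissues, RNA of 4 hens was pooled for one library, messenger RNA was selected with poly-T beads and the second cDNA strand was made with dUTP. The labels call the libraries biological replicates, and each is a pool of hens, so p-values measure the spread between pools and not between single hens.

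The deposited read counts per gene are raw whole numbers made by the authors from their reads, and per the submitters' processing notes the tools were fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 with the genome build GRCg6a. The annotation release, the strand setting of the counting and any filter are not given in the sources used here, so overlapping and antisense genes are uncertain. The deposited FPKM values, given by the authors for the same rows and libraries, were used only to check the counts. The library totals that the FPKM values of rows with over 100 counts imply exceeded the sums of the count columns by 0.0057% to 0.085%. Library totals ran from 23438814 to 29502991. The 10 genes with most counts held 4.20% to 7.55% of a library, and mitochondrial genes 1.66% to 2.12%.

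The file names 12494 of its 20285 rows with a symbol. For 675 others a symbol was taken from the RefSeq table of the assembly GRCg7b through the NCBI gene number in the row's description, for names only, and coordinates are those of the file. Pairs of libraries within a group differed far beyond sampling noise (chi-square over degrees of freedom 23.3 to 114), so no library was counted as a copy of another.

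Genes were tested for heat stress minus thermoneutral with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, the robust quasi-likelihood fit and test, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 15655 genes and took out 4630 rows. The common biological coefficient of variation was 0.174. CPM values use TMM-scaled library sizes, and each value ± SD is over n = 3 libraries. The SE of a log2 change was taken as its absolute value over the square root of the test's F statistic. It is not a standard error given by the fit. Log2 CPM for correlations and principal components used a prior count of 2. At this depth counting error adds to the spread between pools mainly in genes near or under 1 CPM.

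Before the data were examined, 24 function lists and 16 cell type or tissue marker lists, the tests, and the rule for named genes were fixed. Lists with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the function lists and separately over the marker lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, 0 of the 10 function lists and 0 of the 3 marker lists past the threshold kept their call, and fry, which asks if a list's genes move one way on balance, called 2, the proteasome and the glycolysis list. Glycolysis lost its camera call although its estimated correlation was −0.011, under the preset 0.01. A call lost there does not by itself point to correlated genes. Named were the 10 largest rises and 10 largest falls among genes past the threshold with a symbol in the file, a mean of at least 1 CPM and groups that do not overlap. Further named were the 5 rises and 5 falls with the smallest adjusted p among genes with a symbol in the file. Up to 4 members per list that passed were added, by adjusted p. Symbols taken from RefSeq counted only for the lists and the fixed set. Where fewer than 2 members passed, the 2 with the smallest p were eligible. A fixed set completes the rule: HSPA2, HSPA8, HSPH1, HSP90AA1, HSPD1, DNAJA1, HSPA5, CIRBP, HSF1, ESR1, PGR, CA2, CALB1 and AVD. Some genes that the rule names are not reported here.

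The scripts were tested on simulated data made for this comparison over the 15655 genes. Of genes changed by a known fold, 35.8% were recovered at 1.5-fold, 76.1% at 2-fold and 90.9% at 4-fold. Of 149 calls 14 were false (9.4%), a larger share than the threshold of 0.05 aims at. A planted list was found, and 3 of 200 unchanged lists had p under 0.05. Genes were simulated independently of each other, so this does not test camera on lists with correlated members. So in the simulation most changes of 1.5-fold were missed with 3 libraries per group. It made far fewer calls than the 3092 of the real data, so a smaller unadjusted p was needed to pass. The recovered shares therefore do not carry over directly.

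Alternatives were relative log expression and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in all libraries of a group and a mean of 5 CPM), DESeq2 1.42.0, limma-voom, a block on the replicate number, protein-coding genes only, and each library left out in turn. Removal of a trend with gene length (a loess curve per library as an offset) and counts of list members without each library were added after seeing the data. The alternatives planned for a table of FPKM alone were not run, as counts were at hand.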

Results

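RNA from the uterovaginal junction of breeder hens was measured by RNA-seq. This segment of the oviduct lies between the uterus and the vagina and holds the sperm storage tubules, in which sperm are kept between matings. The series set 3 libraries from hens kept at a thermoneutral temperature of 23 °C against 3 libraries from hens exposed to heat stress at 36 °C for 6 h. Each library held pooled RNA of 4 hens, so the 6 libraries stand for 24 hens and a replicate is a pool. The deposited counts summed to 23685672, 23438814 and 24959902 for thermoneutral replicates 1, 2 and 3 and to 25181915, 29502991 and 23944263 for heat stress replicates 1, 2 and 3. Of 20285 rows, 15655 had enough counts to be tested.

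The comparison of the 2 temperatures asked which transcripts of the uterovaginal junction changed under acute heat. Most heat shock genes rose: 27 of 45 tested heat shock proteins and co-chaperones were higher under heat stress, 1 was lower and 17 did not pass. HSP90AA1, the inducible cytosolic HSP90 chaperone, went from 2007 ± 181 to 13220 ± 4875 CPM (mean ± SD, n = 3 libraries per group), a 6.59-fold rise. Genes of the interferon response that passed fell, with 9 of 27 tested members lower and 0 higher, and OASL, an antiviral interferon-induced gene, went from 832 ± 624 to 123 ± 4.80 CPM. Members of the extracellular matrix, glycolysis, proteasome and oxidative phosphorylation lists were also mostly lower among those that passed, while in the list of endoplasmic reticulum chaperones 16 of 35 were higher, 1 was lower and 18 did not pass. No list passed camera with an estimated correlation between genes. The glycolysis list lost its call there at an estimate of −0.011, so such a loss does not by itself point to correlated genes. Fry called 2 function lists, proteasome and glycolysis.

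Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3092 genes (19.8% of those tested), 1602 higher and 1490 lower under heat stress. A change of at least 2-fold was found in 472 of them, of which 136 were higher and 336 lower. All 141 genes named by the rule that passed had all 3 heat stress libraries on one side of all 3 thermoneutral libraries. The rule required this of the largest rises and falls and picked most others by small p, so it is no separate support. Of the 141, 33 passed whichever library was left out (107 without thermoneutral replicate 1, 55 without thermoneutral replicate 2, 84 without thermoneutral replicate 3, 131 without heat stress replicate 1, 98 without heat stress replicate 2 and 37 without heat stress replicate 3). The groups did not overlap in 42.6% of the genes tested, where chance gives 10%. With upper-quartile scaling the split was 1265 higher to 1789 lower. The count depended on single libraries: 1738 genes passed without thermoneutral replicate 1, 445 without thermoneutral replicate 2, 1232 without thermoneutral replicate 3, 1467 without heat stress replicate 2 and 313 without heat stress replicate 3, with at least 2-fold changes in 302, 125, 266, 262 and 89 of them, and a stricter filter on low counts left 250 such changes.

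The libraries of a group resembled each other more than those of the other group, except where heat stress replicate 1 was concerned. Pearson correlations across genes of log2 CPM were 0.9825 to 0.9869 within the thermoneutral group, 0.9741 to 0.9836 within the heat stress group and 0.9618 to 0.9769 between groups. The first principal component held 46.8% of the variance and separated the groups, with scores of −27.1, −31.3 and −33.7 for the thermoneutral libraries, 44.1 and 37.1 for heat stress replicates 2 and 3, and 10.9 for heat stress replicate 1.

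The heat shock list had the strongest set test of the 24 function lists (camera adjusted p = 1.9e-18, median log2 change 0.832). With an estimated correlation between genes, 0.571 in this list, its adjusted p was 0.625. Adjusted over the list alone, 29 members were higher and 2 lower. The largest change was in HSPB8, a small heat shock protein on chromosome 15 (10006078 to 10008129, GRCg6a), with a log2 change of 3.96 (SE 0.64, adjusted p = 0.016), and BAG3, the co-chaperone that binds HSPB8, rose by 3.73 (SE 0.61, adjusted p = 0.0164). The HSP40 co-chaperones DNAJA4 and DNAJB1 rose by log2 changes of 3.93 (SE 0.65) and 2.85 (SE 0.53), and HSPH1, the nucleotide exchange factor of HSP70 chaperones, by 3.76 (SE 0.58). HSPA8 rose from 1299 ± 214 to 6513 ± 2326 CPM, DNAJA1 by 1.99 (SE 0.24), DNAJB6 by 1.11 (SE 0.15) and the mitochondrial chaperonin HSPD1 by 1.75 (SE 0.31).

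**Figure D1:**
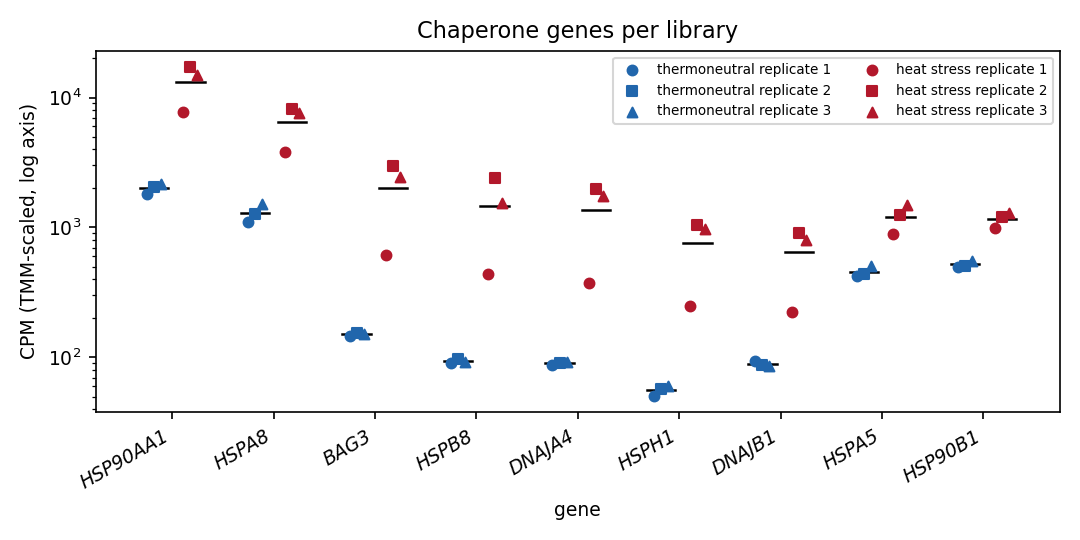
Normalised expression (CPM with TMM scaling, log axis) of 9 chaperone genes in each of the 6 libraries, with a bar at each group mean and one marker shape per replicate number. All heat stress libraries lie above all thermoneutral ones, and heat stress replicate 1 (circles) is the lowest of its group in each gene, for example 18.4% of the way from the thermoneutral mean to the mean of heat stress replicates 2 and 3 for HSPB8.

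The rise was not shared by every chaperone. The member that fell was HSPB7, at a log2 change of −0.71 (SE 0.17, adjusted p = 0.0274), which also belongs to the smooth muscle marker list. HSF1, the main heat shock transcription factor, did not pass, with a log2 change of 0.41 (SE 0.15, adjusted p = 0.095). No row carried the symbol HSPA2, so HSPA2 was not analysed under that name. A row with an HSP70 domain but no symbol rose and is described further below. The number of list members higher was 14 without thermoneutral replicate 1, 6 without thermoneutral replicate 2, 14 without thermoneutral replicate 3 and 6 without heat stress replicate 3. Of the members named above, HSP90AA1, HSPA8, DNAJA1 and DNAJB6 passed in each fit with a library left out, at adjusted p up to 0.0486. HSPB8 and DNAJA4 passed in 2 of the 6 fits with a library left out, with log2 changes between 3.42 and 4.42 and between 3.57 and 4.39.

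Among chaperones of the endoplasmic reticulum and genes of the unfolded protein response, 16 of 35 tested members were higher and 1 lower (median log2 change 0.273), and 18 and 4 adjusted over the list alone. The set test gave an adjusted p of 0.000263 and, with an estimated correlation, an adjusted p of 0.625. HSPA5, the HSP70 of the endoplasmic reticulum, went from 457 ± 45.6 to 1213 ± 306 CPM, and HSP90B1, its HSP90 counterpart, from 521 ± 31.1 to 1160 ± 157 CPM. HERPUD1, a part of the degradation machinery of the endoplasmic reticulum, and CALR, a lectin chaperone, rose 1.58-fold and 1.49-fold. The member that fell was DERL3 at −0.71 (SE 0.14), also on the list of B and plasma cell markers. Higher members numbered 9 without thermoneutral replicate 1, 3 without thermoneutral replicate 2, 9 without thermoneutral replicate 3 and 3 without heat stress replicate 3.

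Outside the chaperone lists, the largest rises among genes with a symbol in the file included MASP1, a serine protease of the lectin pathway of complement (log2 change 5.25, SE 0.98, adjusted p = 0.0176), from a low thermoneutral level of 0.133 ± 0.044 CPM. C8B, a subunit of the terminal complement complex, rose from 1.41 ± 0.115 to 14.2 ± 10.1 CPM, and GKN2, a gastrokine first known from the stomach, from 1.24 ± 0.967 to 19.9 ± 9.94 CPM. KAT2A, a histone acetyltransferase on chromosome 27 (7646435 to 7652243), rose 5.67-fold (SE 0.59 on the log2 scale, adjusted p = 0.038). Its nearest neighbour on the same strand, 980 bp away, is a row without a symbol that rose far more, so reads of the pair are not certain to be separate. The calls of the 10 largest rises among genes with a symbol in the file, 6 of them chaperones, depended on which library was left out. Without thermoneutral replicates 1, 2 and 3 in turn, 1, 1 and 3 passed. Without heat stress replicates 1, 2 and 3 in turn, 10, 7 and 2 passed. All 10 stayed higher in each such fit, with the lowest log2 change 2.11, for KAT2A. That of GKN2 ran from 3.62 to 4.83.

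Further large falls were in GDF2, a bone morphogenetic protein (4.92-fold), R3HDML (4.04-fold) and the polarity protein PARD6A (3.86-fold). Their means were low, going from 1.83, 2.05 and 3.02 CPM to 0.366, 0.505 and 0.784 CPM, where counting error adds to the spread. The transcription factor FEV (3.72-fold), the glycoprotein hormone STC1 (3.70-fold) and DGLUCY (3.56-fold) fell too. Of the 10 largest falls among genes with a symbol in the file, 6 passed without thermoneutral replicate 2, 6 without thermoneutral replicate 3 and 1, TAT, without heat stress replicate 3.

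The rises with the smallest adjusted p among genes with a symbol in the file were moderate in size. They passed in each fit with a library left out, but narrowly in the weakest (adjusted p up to 0.0475). NBEAL1 rose 2.22-fold (log2 change 1.15, SE 0.08, adjusted p = 0.00718), LPAR2, a receptor for lysophosphatidic acid, 2.59-fold (SE 0.11, adjusted p = 0.00722), and TTC17 1.90-fold. AFF4, the scaffold of the super elongation complex of transcription, went from 77.5 ± 0.891 to 126 ± 5.96 CPM, and UBN2, a chromatin protein, from 36.2 ± 2.19 to 70.1 ± 5.62 CPM. The falls with the smallest adjusted p among genes with a symbol in the file passed in each such fit too, also at adjusted p up to 0.0475. SLC5A5, the sodium iodide symporter, fell 2.93-fold, from 48.5 ± 9.33 to 16.6 ± 0.264 CPM. ANGPTL2, a secreted angiopoietin-like protein, fell 2.44-fold, PTGES3L 2.38-fold, DBNDD2 2.03-fold and HERC3, a ubiquitin ligase, 1.87-fold (adjusted p = 0.00722 for each of the falls).

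The interferon list fell with a median log2 change of −0.898 (camera adjusted p = 7.22e-09), and its adjusted p was 0.625 with an estimated correlation. Adjusted over the list alone, 16 members were lower and 0 higher. OASL, DDX60 and ETV7, the last on no list and known as an interferon-induced transcription factor, were the 3 largest falls that the rule named. Their log2 changes were −2.76 (SE 0.60), −2.57 (SE 0.53) and −2.82 (SE 0.53). With a library left out these ran from −3.16 to −1.99, −2.92 to −1.9 and −3.09 to −2.17. The 3 genes passed in 1, 2 and 5 of the 6 such fits. MX1, an antiviral GTPase, went from 213 ± 51.2 to 79.3 ± 21.7 CPM, USP41, which the file describes as ubiquitin specific peptidase 18, from 185 ± 87.7 to 43.5 ± 3.55 CPM, and ZNFX1 fell 1.76-fold. IRF8, an interferon regulatory factor of myeloid cells, fell 1.62-fold with a narrow spread (355 ± 34.1 to 219 ± 5.14 CPM).

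The thermoneutral libraries differed widely in the antiviral genes, as the SD of OASL shows. Lower interferon members numbered 6 without thermoneutral replicate 2, 5 without thermoneutral replicate 3, 5 without heat stress replicate 1, 3 without heat stress replicate 2 and 1 without heat stress replicate 3. Markers of macrophages and dendritic cells were also lower as a set, and a link to the interferon list was not tested. Of 20 markers 4 were lower and 0 higher (10 and 0 adjusted over the list alone, median −0.402, camera adjusted p = 0.00652), and the adjusted p was 0.904 with an estimated correlation. Among them the complement C1q subunits C1QA, C1QB and C1QC fell 1.72-fold, 2.14-fold and 2.00-fold, and VSIG4, a complement receptor of macrophages, fell 1.70-fold. The macrophage count was 1 without thermoneutral replicate 2, 1 without thermoneutral replicate 3, 2 without heat stress replicate 2 and 1 without heat stress replicate 3.

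**Figure D2:**
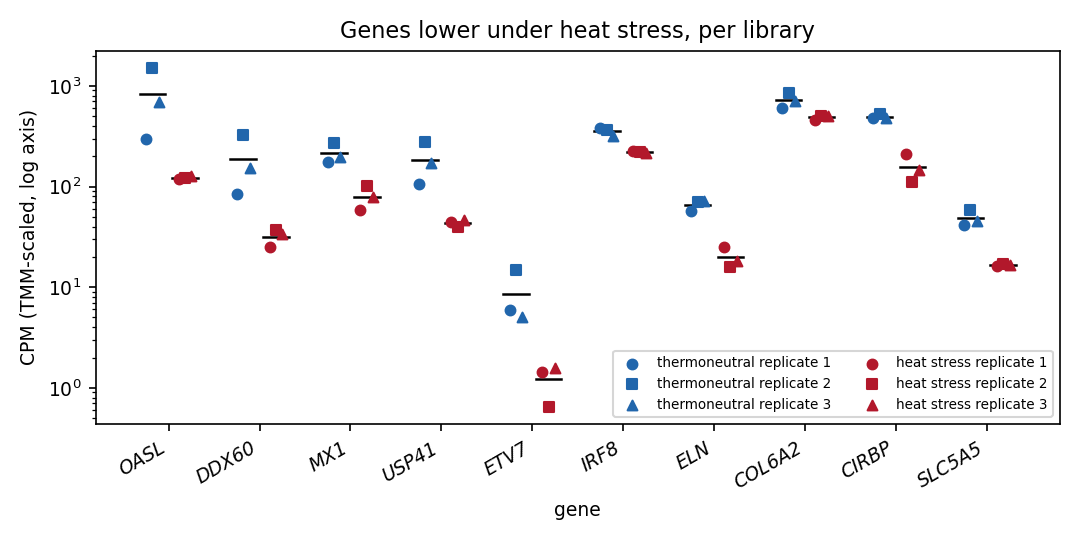
Normalised expression (CPM with TMM scaling, log axis) of 10 genes that fell under heat stress, in each of the 6 libraries, with a bar at each group mean. OASL, DDX60 and ETV7 scatter widely among the thermoneutral libraries, where the SD of OASL is 624 CPM, while IRF8 is tightly grouped.

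Extracellular matrix genes that passed all fell: 11 of 49 tested were lower, and 11 adjusted over the list alone (median −0.230, camera adjusted p = 0.00385; adjusted p = 0.625 with an estimated correlation). ELN, which encodes elastin, fell 3.33-fold, from 65.8 ± 7.97 to 19.8 ± 4.89 CPM. COL6A2 and COL6A3, chains of collagen VI, fell by −0.57 (SE 0.13) and −0.65 (SE 0.16) on the log2 scale, and the small proteoglycan OGN by −0.49 (SE 0.12). Smooth muscle markers were lower as a set (median −0.388, camera adjusted p = 0.00772; adjusted p = 0.904 with an estimated correlation), with 2 of 20 members lower, SYNPO2 and HSPB7, and 2 adjusted over the list alone. Fibroblast markers had 2 of 16 lower, PDGFRA and LUM, and 2 adjusted over the list alone (median −0.255, camera adjusted p = 0.149), and passed the set test without thermoneutral replicate 1 (adjusted p = 0.0129, median −0.327), against a median of −0.114 without thermoneutral replicate 2. The matrix list had 1 lower member without thermoneutral replicate 2 (median −0.147), 1 without thermoneutral replicate 3, 4 without heat stress replicate 1, 2 without heat stress replicate 2 and 1 without heat stress replicate 3. The set test of smooth muscle was lost without thermoneutral replicate 2 (adjusted p = 0.0911), thermoneutral replicate 3 (0.0652) or heat stress replicate 1 (0.207). Lower smooth muscle members numbered 8 without thermoneutral replicate 1 (median −0.552, adjusted p = 2.84e-11), 1 without heat stress replicate 2 and 0 without any other library, with a median of −0.228 without thermoneutral replicate 2.

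Genes of energy metabolism were mostly lower among those that passed. In the glycolysis and glucose list 13 of 33 tested members were lower and 3 higher, and 15 and 3 adjusted over the list alone (median −0.278, camera adjusted p = 0.00437; adjusted p = 0.491 with an estimated correlation). LDHB, a lactate dehydrogenase subunit, fell 1.47-fold, GYS1, the glycogen synthase of muscle and other tissues, 1.63-fold, and FBP1, an enzyme of gluconeogenesis, 1.92-fold. The kinases PDK3 and PDK4, which inhibit pyruvate dehydrogenase, rose 1.34-fold and 2.90-fold. In the oxidative phosphorylation list 11 of 48 were lower and 1 higher, and 13 and 1 adjusted over the list alone (median −0.150, camera adjusted p = 0.00437; adjusted p = 0.739 with an estimated correlation). ATP5O and UQCRQ, subunits of complexes V and III, fell 1.47-fold and 1.35-fold. The member that rose, ATP8, overlaps ATP6 in the mitochondrial genome, so its count is uncertain.

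The 2 metabolic lists did not hold equally well. The oxidative phosphorylation call ended when the trend with gene length was removed (adjusted p = 0.0877) and without heat stress replicate 3 (adjusted p = 0.0556). Lower members of the glycolysis list numbered 7 without thermoneutral replicate 1, 2 without thermoneutral replicate 2, 5 without thermoneutral replicate 3, 5 without heat stress replicate 2 and 0 without heat stress replicate 3, against 5, 1, 4, 5 and 0 for oxidative phosphorylation.

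Of 37 proteasome and ubiquitin genes, 11 were lower and 1 higher, and 18 and 2 adjusted over the list alone (median −0.201, camera adjusted p = 0.00385; adjusted p = 0.625 with an estimated correlation). PSMC2, an ATPase of the regulatory particle, went from 123 ± 2.84 to 75.8 ± 7.16 CPM, and PSMB7, a catalytic subunit, from 163 ± 3.68 to 123 ± 8.26 CPM. UBQLN1, which carries ubiquitylated proteins to the proteasome, rose 1.91-fold. Lower members numbered 18 with upper-quartile scaling, 18 with the stricter filter, 2 without thermoneutral replicate 2, 5 without thermoneutral replicate 3, 4 without heat stress replicate 2 and 1 without heat stress replicate 3.

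The clock list was higher as a set (median 0.215, camera adjusted p = 0.0271; adjusted p = 0.625 with an estimated correlation), with 7 of 22 members higher and 3 lower, the same counts as adjusted over the list alone. CRY1 and CRY2, repressors of the clock, rose 1.76-fold and 1.54-fold and the activator CLOCK 1.57-fold, whereas BHLHE40, a further repressor, fell 1.56-fold. The labels give no sampling time per pool, so a difference in time of day between the groups was not tested. The set test missed the threshold with the length trend removed (adjusted p = 0.051, median 0.172). It also did without thermoneutral replicate 1 (0.066, median 0.221), thermoneutral replicate 3 (0.0812, median 0.178) or heat stress replicate 3 (0.0888, median 0.178). Higher members numbered 2 without thermoneutral replicate 2 and 2 without heat stress replicate 3.

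Cell cycle genes were lower as a set (median −0.270, camera adjusted p = 0.0176; adjusted p = 0.625 with an estimated correlation), with 4 of 47 members lower, TPX2, RRM1, BUB1B and NUSAP1, and 3 adjusted over the list alone. TPX2, a spindle assembly factor, fell 2.00-fold, and RRM1, a subunit of ribonucleotide reductase, 1.85-fold. The test was lost without thermoneutral replicate 2 (adjusted p = 0.0545) or heat stress replicate 1 (0.132, median −0.173). Lower members numbered 1 without thermoneutral replicate 2, 1 without heat stress replicate 3 and 2 without any other library, and TPX2 passed in all 6 such fits, RRM1 in 2, BUB1B in 1 and NUSAP1 in 0. Cholesterol genes were also lower as a set (median −0.365, camera adjusted p = 0.0176; adjusted p = 0.739 with an estimated correlation), while only 4 of 25 members passed, in both directions, and 0 adjusted over the list alone. MVD and HSD17B7, enzymes of the synthesis pathway, fell 1.46-fold and 1.56-fold. NR1H3, the liver X receptor alpha, and ABCA1, a cholesterol exporter, rose 1.37-fold and 1.31-fold. This set test was lost without thermoneutral replicate 1 (adjusted p = 0.0791), thermoneutral replicate 3 (0.0629) or heat stress replicate 2 (0.0919, median −0.238), and lower members numbered 12 without heat stress replicate 1 (median −0.553) and 0 without any other library. With the replicate block 1 cholesterol gene was higher and 6 were lower.

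Ciliated epithelium markers that passed were lower, with 8 of 26 tested members lower and 0 higher, also when adjusted over the list alone (median −0.244, camera adjusted p = 0.0114; adjusted p = 0.904 with an estimated correlation). CCDC113 fell 1.90-fold, SPAG16 1.61-fold, CFAP126 1.40-fold and CFAP43 1.39-fold, all parts of motile cilia. The set test was lost without thermoneutral replicate 1 (adjusted p = 0.272, median −0.149) or heat stress replicate 3 (0.0763, median −0.140), and lower members numbered 3 and 1 there, 1 without thermoneutral replicate 2 and 4 without heat stress replicate 2.

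**Figure D3:**
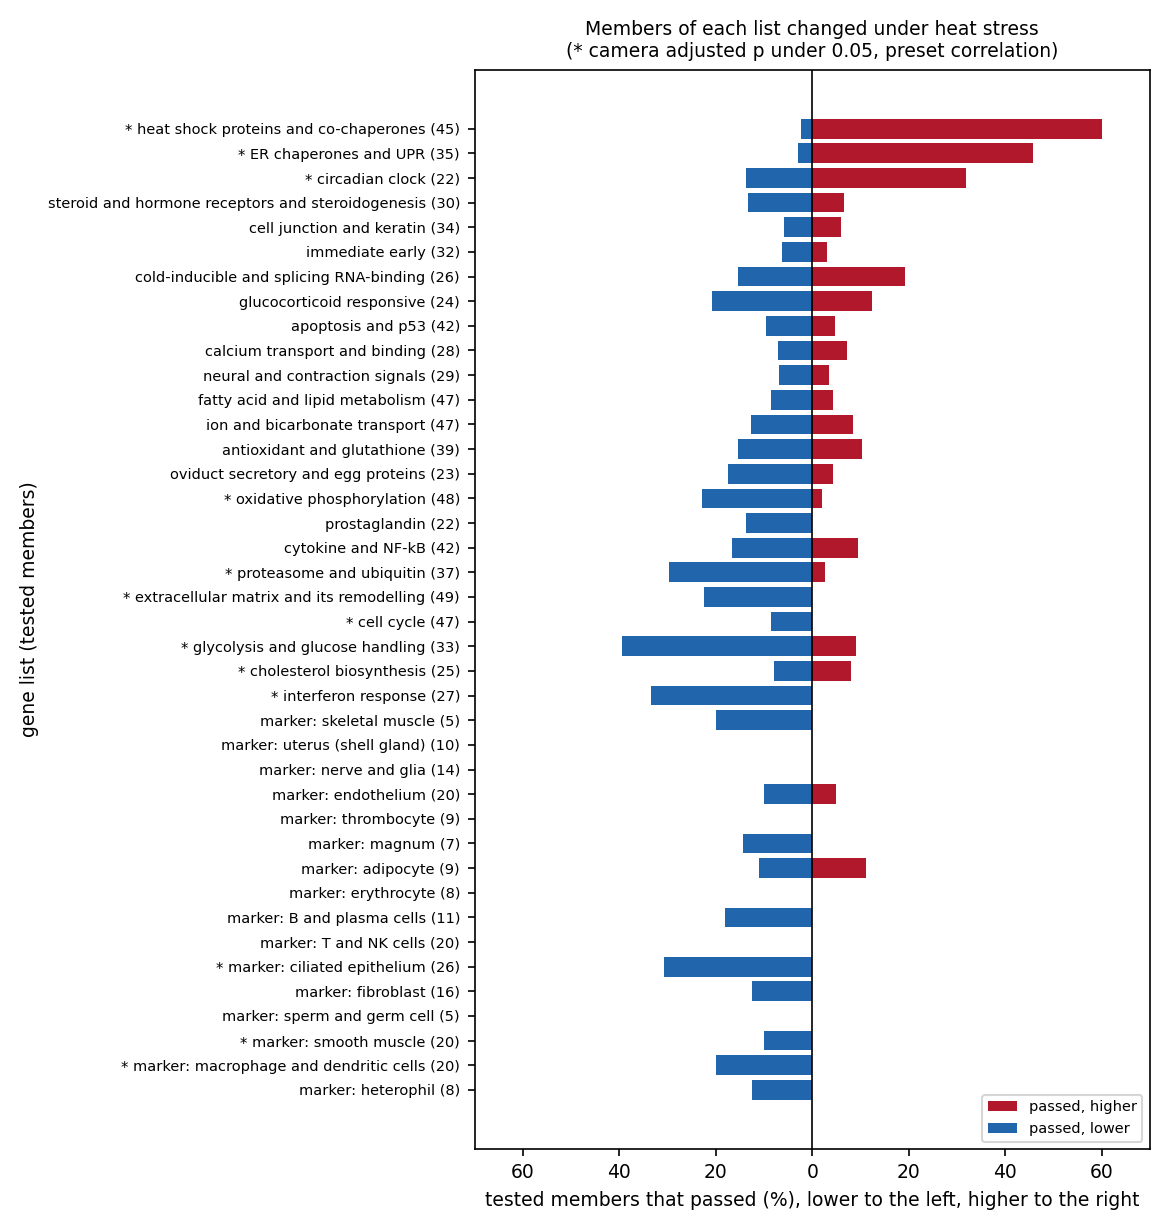
Share of the tested members of each of the 24 function lists and 16 marker lists that passed (edgeR adjusted p under 0.05), higher to the right in red and lower to the left in blue, with the number tested in brackets. The heat shock list has 27 of 45 members higher, and the glycolysis list has 13 of 33 lower.

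The remaining function lists did not pass the set test, and their members that passed went both ways in most. In each of these lists at most 2 members were higher and 2 lower without thermoneutral replicate 2, and at most 1 higher and 2 lower without heat stress replicate 3. Among the 26 genes of cold-inducible and splicing RNA-binding proteins, 5 were higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.685), and 2 and 4 with upper-quartile scaling or the replicate block. CIRBP, the cold-inducible RNA-binding protein, fell 3.16-fold, from 495 ± 22.7 to 157 ± 51.4 CPM, and HNRNPDL fell 1.82-fold. The splicing factor SRSF10 rose 1.44-fold and the kinase CLK1, which phosphorylates such factors, 1.58-fold. CIRBP, HNRNPDL and CLK1 lost their call without heat stress replicate 3, at adjusted p values up to 0.0518.

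Antioxidant genes had 4 of 39 higher and 6 lower (5 and 8 adjusted over the list alone; camera adjusted p = 0.661). GPX1, a glutathione peroxidase, rose from 1016 ± 70.3 to 2471 ± 733 CPM and GCLC, the catalytic subunit of glutathione synthesis, 1.61-fold. GPX7 and MGST3 fell 2.12-fold and 1.65-fold. Glucocorticoid-responsive genes had 3 of 24 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.953, with a positive median of 0.042 and a negative mean of −0.015). TAT, tyrosine aminotransferase, fell 4.09-fold, from a low 3.35 ± 0.410 to 0.815 ± 0.220 CPM. KLF9 fell 2.59-fold and MAP3K6 1.52-fold. PDK4 rose from 6.92 ± 0.235 to 20.1 ± 8.51 CPM, and the glucocorticoid receptor NR3C1 rose 1.49-fold. Without heat stress replicate 3, TAT alone of the 4 glucocorticoid-responsive genes named by the rule passed, and 2 of them passed without thermoneutral replicate 2.

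Of 42 cytokine and NF-kB genes, 4 were higher and 7 lower (4 and 8 adjusted over the list alone; camera adjusted p = 0.424). IL1R1, TGFB2 and the chemokine receptor CXCR4 rose 1.78-fold, 1.64-fold and 2.40-fold, and the receptor TLR2-1 fell 1.85-fold. None of these 4 genes passed without thermoneutral replicate 2 or without heat stress replicate 3, and 2 of them passed without thermoneutral replicate 3. Immediate early genes had 1 of 32 higher, ZFP36L1 at 1.72-fold, and 2 lower, RHOB and KLF2 (also adjusted over the list alone; camera adjusted p = 0.436). Apoptosis and p53 genes had 2 of 42 higher and 4 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.913), with CFLAR, an inhibitor of caspase-8, at 1.33-fold higher and TP53I3 at 2.52-fold lower. The apoptosis list had 1 higher and 0 lower without thermoneutral replicate 1, 0 and 0 without thermoneutral replicate 2, and 8 and 3 without heat stress replicate 1.

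Genes tied to the fluid and secretions of the oviduct changed in both directions. Ion and bicarbonate transport genes had 4 of 47 higher and 6 lower (also adjusted over the list alone; camera adjusted p = 0.424). The water channel AQP1 rose 1.61-fold, while the carbonic anhydrase CA12, the proton pump subunit ATP6V1C2 and the proton channel HVCN1 fell 2.29-fold, 1.88-fold and 1.57-fold. CA2, the cytosolic carbonic anhydrase, did not pass (log2 change 0.21, SE 0.07, adjusted p = 0.074). Calcium genes had 2 of 28 higher, ATP2C1 and STIM2, and 2 lower, S100A10 and S100A11 (1 and 2 adjusted over the list alone). The camera adjusted p was 0.953, with a median of 0.026 and a mean of −0.021. No row carried the symbol CALB1, so CALB1 was not analysed under that name. Oviduct secretory and egg protein genes had 1 of 23 higher, AGR2 at 1.45-fold, and 4 lower (also adjusted over the list alone; camera adjusted p = 0.424), among them RBP, SERPINB12 and FABP3 at 1.89-fold, 2.39-fold and 1.68-fold. AVD, the egg-white protein avidin, had a log2 change of 0.54 (SE 0.83, adjusted p = 0.68), and −0.61 without heat stress replicate 1.

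Steroid receptors and steroidogenic genes had 2 of 30 higher and 4 lower (also adjusted over the list alone; camera adjusted p = 0.685). SULT1E1, which inactivates estrogens by sulfation, fell 1.79-fold and CYP11A1, the first enzyme of steroid synthesis, 1.46-fold. The estrogen receptor ESR1 and the progesterone receptor PGR did not pass, at log2 changes of −0.31 (SE 0.12, adjusted p = 0.102) and 0.18 (SE 0.10, adjusted p = 0.246). Prostaglandin genes had 3 of 22 lower, the receptors PTGDR and TBXA2R and the transporter SLCO2A1, and 0 higher (also adjusted over the list alone; camera adjusted p = 0.424). Lipid metabolism genes had 2 of 47 higher and 4 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.414), with PPARA 1.73-fold higher and LIPG 2.24-fold lower. Cell junction and keratin genes had 2 of 34 higher, TJP1 and PKP1, and 2 lower, TJP3 and KRT6A (1 and 2 adjusted over the list alone; camera adjusted p = 0.424). Neural and contraction signals had ROCK2 higher and NOS3 and NPY1R lower among 29 (0 and 0 adjusted over the list alone; camera adjusted p = 0.673, with a median of −0.031 and a mean of 0.031).

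Other marker lists did not pass. T and NK cell markers had 0 of 20 passing, erythrocyte markers 0 of 8, thrombocyte markers 0 of 9, nerve and glia markers 0 of 14, sperm and germ cell markers 0 of 5, and uterus markers 0 of 10, the same counts as adjusted over the list alone. B and plasma cell markers had 2 of 11 lower, BTK and DERL3, heterophil markers 1 of 8, EXFABP, magnum markers 1 of 7, SERPINB12, and skeletal muscle markers 1 of 5, ACTA1 (also adjusted over the list alone). Endothelial markers had PROX1 higher and EGFL7 and ROBO4 lower among 20 (also adjusted over the list alone), and adipocyte markers CIDEA higher and LIPE lower among 9 (1 and 2 adjusted over the list alone). Camera adjusted p values of these lists ran from 0.194 for heterophils to 0.958 for nerve and glia. Without heat stress replicate 3, 0 members of these lists passed, while the set test of T and NK cells passed there (adjusted p = 0.0371, median −0.302, against −0.156 with all libraries). The erythrocyte gene HBBA stood at 37.1 ± 8.35 CPM in the thermoneutral and 23.0 ± 6.36 CPM in the heat stress libraries (adjusted p = 0.0891).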

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

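The removal of the length trend and the counts of list members without each library were chosen after the data were seen, and the other alternatives before. The count of genes changed under heat stress, 3092 as reported, ran from 2722 to 3926 over both scalings, both filters, DESeq2, limma-voom, the replicate block, protein-coding genes and the length trend, with 0 genes of opposite sign among the shared calls. Without one library, genes changed ran from 313 to 3690, higher genes from 151 to 2011, lower genes from 162 to 1679, changes of at least 2-fold from 89 to 697 and named genes from 37 to 131 of 141, each lowest without heat stress replicate 3 and highest without heat stress replicate 1. Such fits have fewer libraries and fewer calls are possible, and the cause of the rise without heat stress replicate 1 was not tested. Without thermoneutral replicate 2 445 genes passed. The stricter filter left 250 changes of at least 2-fold, from fewer genes tested. Of the 10 function lists, 8 to 9 passed without one library, 8 with the length trend removed, 2 with fry and 0 with an estimated correlation. Calls were lost there whether the estimate was high (0.759 for interferon) or near 0 (−0.011 for glycolysis). The loss therefore cannot tell which calls rest on correlated genes. The gap between mean correlations within and between groups was 0.0119, and 0.0786 over the 500 most variable genes, which by construction hold more of the difference.

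With the replicate block 2722 genes were called, 1291 higher and 1431 lower, and 10 function lists passed. Lower members of some lists also moved by over 1.5 times: interferon from 9 to 15 with the block and 17 with DESeq2, oxidative phosphorylation from 11 to 6 with the block, cholesterol from 2 to 6 and smooth muscle from 2 to 5 with the block, macrophage from 4 to 10 and ion transport from 6 to 10 with DESeq2, and in the matrix list 3 members were higher with DESeq2. Replicate numbers showed no clear pairing of the libraries. Deviations from the group means of same-numbered libraries correlated at −0.05, 0.25 and 0.07, and not every library matched its own number best. With 3 libraries per group only 3 such correlations exist, so a pairing cannot be excluded.

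Lists whose set test pointed the other way under some alternative were all past no threshold in the main test, and the cause was not tested. Their median log2 changes over the fits without one library ran from −0.128 to −0.05 for antioxidant, −0.018 to 0.065 for apoptosis and p53, −0.021 to 0.156 for immediate early, 0.009 to 0.143 for glucocorticoid responsive, 0.061 to 0.164 for cold-inducible and splicing, 0.014 to 0.041 for calcium, −0.062 to 0.146 for neurotransmission and contraction, −0.046 to 0.554 for skeletal muscle, −0.16 to 0.018 for thrombocyte and −0.069 to 0.066 for nerve and glia genes. The direction also turned for glucocorticoid responsive (0.042) and calcium (0.026) genes under fry, for calcium (−0.006) with the length trend removed and for thrombocyte (−0.056) with the replicate block. The log2 change of AVD ran from −0.608 to 1.249 without one library. Over the named genes and the alternatives, 1227 values stayed on their side of the threshold, 361 lost and 9 gained a call. Depth limits calls of genes near 1 CPM.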

Other observations

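Gene families were looked at by the protein domain that the file gives per gene, a choice made after the data were seen; the tests of the length trend, of read-through and of other splits were written before their results, and those on heat stress replicate 1 after. Of 223 domain families with at least 8 tested genes, 13 passed camera with the preset correlation, and each had an adjusted p of 0.719 with an estimated correlation. With the length trend removed 5 of the 13 lost their call: Beach (0.102), Proteasome (0.0987), OTU (0.0533), PI3_PI4_kinase (0.268) and Sulfotransfer_1 (0.0533). Among chromatin readers with a bromodomain 13 of 25 were higher and 0 lower (median log2 change 0.344, adjusted p = 0.000113, and 0.0043 with the length trend removed). Among them BRD1, BAZ1B, PHIP and BRD2 had log2 changes of 0.52 (SE 0.07), 0.59 (SE 0.10), 0.67 (SE 0.12) and 0.43 (SE 0.11). Genes with a BTB domain, many of them zinc finger repressors, had 21 of 73 higher and 2 lower (adjusted p = 0.00302), including ZBTB21 at 0.65 (SE 0.09), ZBTB33 at 0.62 (SE 0.10) and BCL6 at 0.42 (SE 0.11).

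Enzymes with the enoyl-CoA hydratase fold, which act in the breakdown of fatty acids and branched amino acids, had 6 of 10 lower and 0 higher (median −0.425, adjusted p = 0.00345), with ECH1 at −1.36 (SE 0.26), ECHDC2 at −0.82 (SE 0.11) and AUH at −0.63 (SE 0.09). Genes with a collagen domain had 10 of 43 lower and 0 higher (adjusted p = 0.00649), 3 of them the C1q subunits. The 3 largest rises of all lay in rows without a symbol. On chromosome 27 (GRCg6a) ENSGALG00000023819 (7653224 to 7653761, pseudogene) went from 0.924 ± 0.614 to 1182 ± 889 CPM, and ENSGALG00000023818 (7654604 to 7655550, pseudogene, other strand) from 86.7 ± 54.2 to 3807 ± 2804 CPM. The lncRNA ENSGALG00000050749 on chromosome 13 went from 1.33 ± 0.782 to 72.8 ± 63.6 CPM. Also without a symbol, on chromosome 5, ENSGALG00000011715 (53057972 to 53060373), a pseudogene with an HSP70 domain, went from 1267 ± 133 to 7303 ± 4459 CPM, and its reads are uncertain, as HSP70 copies are alike.

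Each of the 10 splits of the 6 libraries into 3 and 3 was fitted. The real one gave 3092 genes and the highest other gave 1. As many were given by 1 of 10 splits, which is too few splits for a share under 0.05. Each other split mixes the 2 groups on both sides, so any heat difference widens the spread within its sides. Few calls are then left in any case, so the contrast of 3092 with 1 is no support for the groups.

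Heat stress replicate 1 rose less in heat shock genes than the other libraries of its group. On the linear scale, 23 heat shock genes that were called higher at least 2-fold without it lay at a median of 31.4% (quartiles 19.4% and 39%) of the way from the thermoneutral mean to the mean of heat stress replicates 2 and 3. Dilution with RNA of unheated tissue would give falling genes that same share, but 393 genes that fell lay at 69.3%, with a lower quartile of 54.3%, which argues against dilution as the whole cause. The 197 other genes that rose lay at 31.8% (quartiles 13.7% and 52.7%), close to the heat shock genes, as dilution needs, so dilution as part of the cause stays open. Its total of 25.2 M counts, against 23.9 M and 29.5 M for heat stress replicates 3 and 2, was not the lowest of its group, which argues against depth. A weaker or differently timed heat response of its 4 hens may explain it and was not tested.

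Shorter genes were lower and longer genes higher under heat stress by their medians: the median log2 change went from −0.1 to 0.097 between the shortest and the longest of 10 equal bins of genes (median lengths 593 and 5771 bp). The lengths are those of the file, which gave the deposited FPKM values in only 61.7% of rows with a count in thermoneutral replicate 1 (within 0.01%), so the trend and its removal are uncertain where the lengths differ. With the trend removed per library, the proteasome list kept its call (adjusted p = 0.0291, median −0.201 before and −0.165 after) and so did the glycolysis list (0.00363, −0.278 and −0.257), so the trend is not the whole cause of either list's fall. The 13 genes with a Proteasome domain, of which 7 were lower, lost their call (0.0162 before and 0.0987 after). Their median after removal was not analysed here, so a smaller change is not shown and the trend stays open for these. The oxidative phosphorylation list, with a median length of 1007 bp, lost its call (0.0877). The call ended as its median went from −0.150 (quartiles −0.241 and −0.081) to −0.108 (quartiles −0.195 and −0.018), nearer to 0 with no narrower spread. Without heat stress replicate 3 it also ended, at a median of −0.142, so a smaller change is not shown to be the only reason, and length and heat cannot be told apart there. RNA integrity, which could give such a trend, was not analysed here.

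KAT2A rose next to ENSGALG00000023819, which ends upstream of it on the same strand. Its gain in CPM was 18.2%, 19.6% and 20.1% of the gain of that row in heat stress replicates 1, 2 and 3. Transcripts that run through the end of the row into KAT2A may explain this, and so may shared regulation. Among same-strand neighbours within 10 kb of the 31 genes that rose at least 4-fold, 8 lay downstream and 8 upstream. The downstream minus the upstream median log2 change was −0.09 (exact one-sided permutation p = 0.723). KAT2A is itself among the 31, so the row counted among the upstream genes and KAT2A among the downstream genes. These are also too few genes with too wide a spread to decide. Read-through therefore cannot be told apart from regulation of KAT2A itself.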
